A study of Mus musculus with 6 samples.

How the data were processed

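Cells of the mouse spermatocyte-derived line GC-2 spd(ts) were sequenced after 48 h with 120 µM bisphenol A (BPA) or with its vehicle, 0.1% dimethyl sulfoxide. Per the labels' protocols, the RNA of each culture was divided among a library of circular RNA (circRNA, after removal of ribosomal RNA and digestion of linear RNA with RNase R), a small RNA library for microRNA (miRNA) and an mRNA library made with Illumina's TruSeq procedure. Each of the 6 libraries was the only one of its group. Groups came from the titles and treatment labels of the samples.

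Per the submitters' processing notes, STAR was named for the circRNA and mRNA libraries and StringTie for the mRNA libraries, with no version, Bowtie 1.1.0 was named for the miRNA libraries, and the builds GRCm38 and mm10 were named for all of them. The read counter, the circRNA caller, the miRNA caller, the annotation release and the filters are not given in the sources used here.

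The deposited mRNA values were log2 values. In all 22127 genes of both libraries, 2 to the power of the value, less 1, was a whole multiple of 1 step per library within a tolerance of 0.001. That step was 1.03943 in the control library and 0.962066 in the BPA library, so whole reads were recovered for 100% of the values by dividing by it. The steps were the inverse of median-of-ratios size factors as DESeq2 1.42.0 computes them on the recovered reads, and the authors' scaling was kept as deposited. The deposited circRNA values were log2 values as well, and 2 to the power of the value, less 1, divided by 2, was a whole number within the same tolerance of 0.001 in all 9158 circRNAs of both libraries. A step of 2 was taken as 1 back-splice event. What made every event count 2 is not given in the sources used here, and if a step of 2 stood for 2 reads, the counting intervals given here would be wider than needed. The deposited miRNA values were whole read counts in 931 miRNAs, and beside them stood TPM columns in which the authors had divided each count by the library's total, per the file headers and the values. The TPM columns were not used in any test. Tables of the authors' comparisons also held p-values and adjusted p-values, per the file headers, from a test of 1 library against 1 whose name is not given in the sources used here. They are quoted as the authors' deposited values only. The authors' deposited log2 fold change of the miRNA table was the control over BPA, opposite in sign to the other tables, and 266 of its cells were not numbers and 74 were infinite. All ratios here are BPA over control.

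The designed comparison of mRNA and circRNA expected counts. Since the values were on a log2 scale, the mRNA ratio was computed from the deposited normalised values with a pseudocount of 1, the setting fixed for normalised values, and the circRNA ratio from back-splice events with 0.5 events added. The miRNA ratio was computed from counts with 0.5 reads added. Counts of circRNA and miRNA were scaled with the trimmed mean of M-values (TMM) of edgeR 4.0.16 in R 4.3.3, whose factors were 0.558 and 1.79 for the control and BPA miRNA libraries and 1.06 and 0.942 for the circRNA libraries. A feature was compared when it had at least 10 reads or events in both libraries together, with the recovered reads used for mRNA, which left 16870 mRNA genes, 464 miRNAs and 457 circRNAs. A ratio of at least 2 in either direction was counted. Because there was 1 library per group, no test across conditions was made and no p-value was computed. For each ratio an exact conditional binomial (Clopper-Pearson) 95% interval was computed with SciPy 1.17.1, which compares the reads of 2 libraries and leaves out the error of the scaling. For a feature at 0 in a library, a fold was computed with 3 counts per library in place of 0. It took the count of the other library as exact, so the counting interval can reach a smaller fold.

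A list of genes was described by the median log2 ratio of its members past the filter and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. At least 5 measured genes, or 3 measured miRNAs, were required. A list was said to stand apart with a percentile under 2.5 or over 97.5, as a description of these libraries, since genes are not replicates. There were 38 gene lists and 18 miRNA families or clusters. They covered stress responses, cell cycle, metabolism, chromatin, signalling, small RNA and circRNA factors, and markers of testis and other cell types. The lists, filters, thresholds, scalings and the rule for naming genes were chosen before the data were examined. Of mRNA, the rule took in each direction the 10 genes with the largest absolute log2 ratio among those with at least 100 reads in the higher library, leaving out predicted genes, clones with AC or AL names, small RNA genes, ribosomal RNA and pseudogenes by symbol, and up to 4 members of each list that stood apart and 2 of each other list, with 4 for the miRNA and circRNA factors. Of miRNA it took 8 in each direction with at least 50 reads in the higher library, the 5 most abundant in the control and 2 per family. Of circRNA it took 8 in each direction with at least 30 events together, the 5 most abundant in the control and up to 6 from a fixed list of hosts. Some features that the rule took are not reported here. Further members of lists are named here as examples of their list after their values were seen.

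Coordinates are on GRCm38. Those of circRNAs are from the deposited identifiers, those of genes from GENCODE M21, which held 22036 of the 22127 mRNA gene identifiers, and those of mature miRNAs from RefSeq GRCm38.p6, which also gave the miRNA sequences. Exons shared by genes on the same strand were found with bedtools 2.31.1. An all-or-none gene was searched for near-identical copies with blastn 2.17.0, at 95% identity over at least 50% of its longest transcript. Trends of the mRNA ratios on GC content and transcript length were removed by subtracting the median ratio of 50 bins of genes. Sites of miRNA seeds were searched in annotated 3′ untranslated regions. Tables were handled with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

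The steps were tested on simulated data drawn from the real levels and depths, with seeded changed features. Counts were drawn with counting error alone, and differences between cultures or library preparations were left out. The shares of unchanged features counted and the coverage of the intervals therefore do not include such differences. In simulated mRNA libraries 96% of 50 genes changed 3-fold and 6.12% of 49 genes changed 1.5-fold were counted as at least 2-fold, and so were 2.07% of 16681 unchanged genes. In simulated miRNA libraries 44 of 44 miRNAs changed 3-fold were counted, with 6.16% of 292 unchanged ones. In simulated circRNA libraries 77.5% of 40 circRNAs changed 3-fold were counted, with 20.3% of 320 unchanged ones, so counting and scaling error gave many circRNA ratios of 2-fold. The median of those unchanged circRNAs was 0.14 in place of 0. The intervals held the true ratio for 95.6% of mRNA genes, 95.6% of miRNAs and 94.8% of circRNAs with the estimated scaling. Lists of 25 real mRNA genes raised by 0.5 stood apart in 200 of 200 draws, and lists of 8 real miRNAs raised by 0.5 in 76 of 200, so a shift of that size in a miRNA family would mostly be missed.

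Alternatives changed the scaling, the pseudocount (5 times smaller and 5 times larger), the filter (none and 5 times stricter) and the counting-error requirement, summed features that share a symbol, and thinned the deeper circRNA library. Chosen after seeing the data were TMM scaling of the recovered mRNA reads, the omission of mRNA genes that overlap another gene, the omission of list members shared with the ATF4 list, a circRNA filter of 5 events and a restriction to miRNAs with a miRBase-style name. The tables held 0 columns of other samples. No raw reads were used here.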

Results

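GC-2 spd(ts) is a mouse line made from spermatocytes, the male germ cells that enter meiosis, by immortalisation with a viral large T antigen and a temperature-sensitive p53. The cells were kept without serum for 12 h and then for 48 h in medium with 10% serum and either 120 µM BPA, a monomer of polycarbonate plastic that can bind estrogen receptors, or 0.1% dimethyl sulfoxide as control. RNA of each culture was sequenced as mRNA, as miRNA and as circRNA, the covalently closed RNA formed by back-splicing. The mRNA libraries held 32312872 reads in control and 33071378 with BPA, and 19887 and 20590 of the 22127 listed genes were above 0. The miRNA libraries held 3927981 and 3452574 reads, and the circRNA libraries held 12909 and 17586 back-splice events. A count of 0 allows up to 0.0928 and 0.0907 CPM (reads scaled by the library total) in the mRNA libraries, 0.764 and 0.869 CPM in the miRNA libraries, and 0.0232% and 0.0171% of the events in the circRNA libraries. Each comparison set 1 BPA library against 1 control library, so no difference has a replicate check, and any other difference between the cultures is part of it. The intervals and limits cover counting error only, since reads from PCR without molecular identifiers are not independent molecules.

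The mRNA comparison asked which transcripts differed between exposed and vehicle-treated cells. Genes of the integrated stress response, which the transcription factor ATF4 switches on when translation or amino acid supply is disturbed, were higher in the BPA library. All 36 measured members had a log2 ratio above 0, 20 of them at least 2-fold, and their median was 1.09. Trib3, a pseudokinase that restrains the response (chromosome 2, 152337422 to 152344032), had 985 reads in control and 6890 with BPA, a log2 ratio of 2.69 (95% interval 2.60 to 2.79). Chac1, which degrades glutathione (chromosome 2, 119351229 to 119354381), had 535 and 2709 reads and a ratio of 2.23 (2.09 to 2.37). The stress cytokine Gdf15 (chromosome 8, 70629393 to 70632456) had 15 and 131 reads and 2.94 (2.24 to 3.89), and the hormone Fgf21 had 5 and 38 reads and 2.60 (1.47 to 4.52). Cth, an enzyme of cysteine synthesis, was at 2.12 and Ddit3, the pro-apoptotic factor CHOP, at 1.54. Of the serine synthesis enzymes, Psph was at 1.44, Psat1 at 0.68 and Phgdh, the lowest member of the list, at 0.51, and Atf4 itself was at 0.69. No random list of the same size and expression had so high a median, and their central 95% ran from -0.16 to 0.04.

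Other protective programmes were also higher in the BPA library, with smaller medians. Of 26 measured targets of NRF2, the regulator of antioxidant defence, 5 were at least 2-fold higher, none 2-fold lower and 21 within 2-fold, with a median of 0.43. The cystine importer Slc7a11 (chromosome 3, 49892526 to 50443614) was at 2.02, the autophagy receptor Sqstm1 at 1.36, the quinone reductase Nqo1 at 1.31 and the heme oxygenase Hmox1, with 13135 and 31917 reads, at 1.17. Ugt1a6a was at 2.22, and its exons overlap those of other Ugt1a genes. Endoplasmic reticulum chaperones and degradation factors had a median of 0.30, with 22 of 25 above 0. Dnajb9 at 1.34 and Herpud1 at 1.06 were the 2-fold members, and the chaperone Hspa5 was at 0.69. Lysosome and autophagy genes had a median of 0.28, with 30 of 31 above 0, and Sqstm1 was the 1 member at 2-fold, followed by Atg12 at 0.58, Becn1 at 0.57 and Ctsl at 0.56. These medians stood above those of all random lists. Cytosolic heat shock genes lay the other way, with 18 of 20 below 0, none at 2-fold and a median of -0.24 at percentile 1.31, with Hsph1 at -0.55 and Hspa8 at -0.33. With the trend of the ratios on GC content removed, the heat shock list lay inside the random range, at percentile 5.12. Its median was little changed, at -0.23.

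Targets of p53 and interferon-response genes were higher as lists. Of 27 measured p53 targets 7 were at least 2-fold higher, none lower, and the median was 0.34 at percentile 99.99. The growth-arrest genes Gadd45a and Cdkn1a were at 2.20 and 1.51, Trp53inp1 at 2.13 and Sesn2, also an ATF4 target, at 1.67, while Mdm2 was at 0.25 and Plk2 at -0.60. Of 27 measured interferon-response genes 8 were at least 2-fold higher and none lower, with a median of 0.59. The regulator Irf7 (chromosome 7, 141262706 to 141266481) had 38 and 164 reads and a ratio of 1.97 (1.48 to 2.55), Rsad2 was at 1.81 and Isg15 at 1.35, whereas Ifit2 was at -0.14 and Psmb8 at -0.16. Ifi44, with 0 and 10 reads, was 3.09-fold higher with 3 counts in place of 0, and its interval began at a log2 ratio of 1.05. With the members shared with the ATF4 list left out, the medians were 0.43 over 25 NRF2 targets and 0.31 over 26 p53 targets, at percentiles 100 and 99.99. Nearly all members stayed in place, so this does not show the rise of these lists to be separate from the ATF4 response. Sertoli cell markers had a median of 0.48 over 10 genes at percentile 98.0, with Amh at 1.52 and Wt1 at 1.48 from 33 and 26 reads with BPA, and Inhbb at -1.05. That list lay inside the random range with a pseudocount 5 times larger, and with a stricter filter, where its percentile was 97.4 over 6 genes.

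Genes of the contractile and matrix programme of fibroblast-like cells were lower in the BPA library. Of 19 actin cytoskeleton genes, targets of the factor SRF, 18 were below 0 and 5 at least 2-fold lower, with a median of -0.76. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), had 10324 and 4340 reads and a ratio of -1.36 (-1.41 to -1.31), Tagln was at -1.12 and Myl9 at -1.19, and the abundant Actb was at -0.47. TGF-β targets had a median of -0.74 over 14 genes, 5 of them 2-fold lower, including the growth factor Bmp4 (chromosome 14, 46383520 to 46390669) with 1982 and 375 reads and a ratio of -2.51 (-2.68 to -2.35). Extracellular matrix and adhesion genes had a median of -0.49 over 32, with 30 below 0 and 5 at least 2-fold lower. The adhesion protein Thbs1 was at -1.45, and the collagens Col1a1 and Col1a2 at -1.12 and -1.09, while Fn1 was at -0.04 and Thbs2 at 0.53. Peritubular and fibroblast markers had a median of -0.61 over 10 genes, with Pdgfrb at -0.93, Twist2 at -0.88 and S100a4 at -0.63. Acta2 belongs to 3 of these lists and Tagln to both the TGF-β and the actin list, so the lists are not independent. No random list had medians as low as any of the 4.

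**Figure D1:**
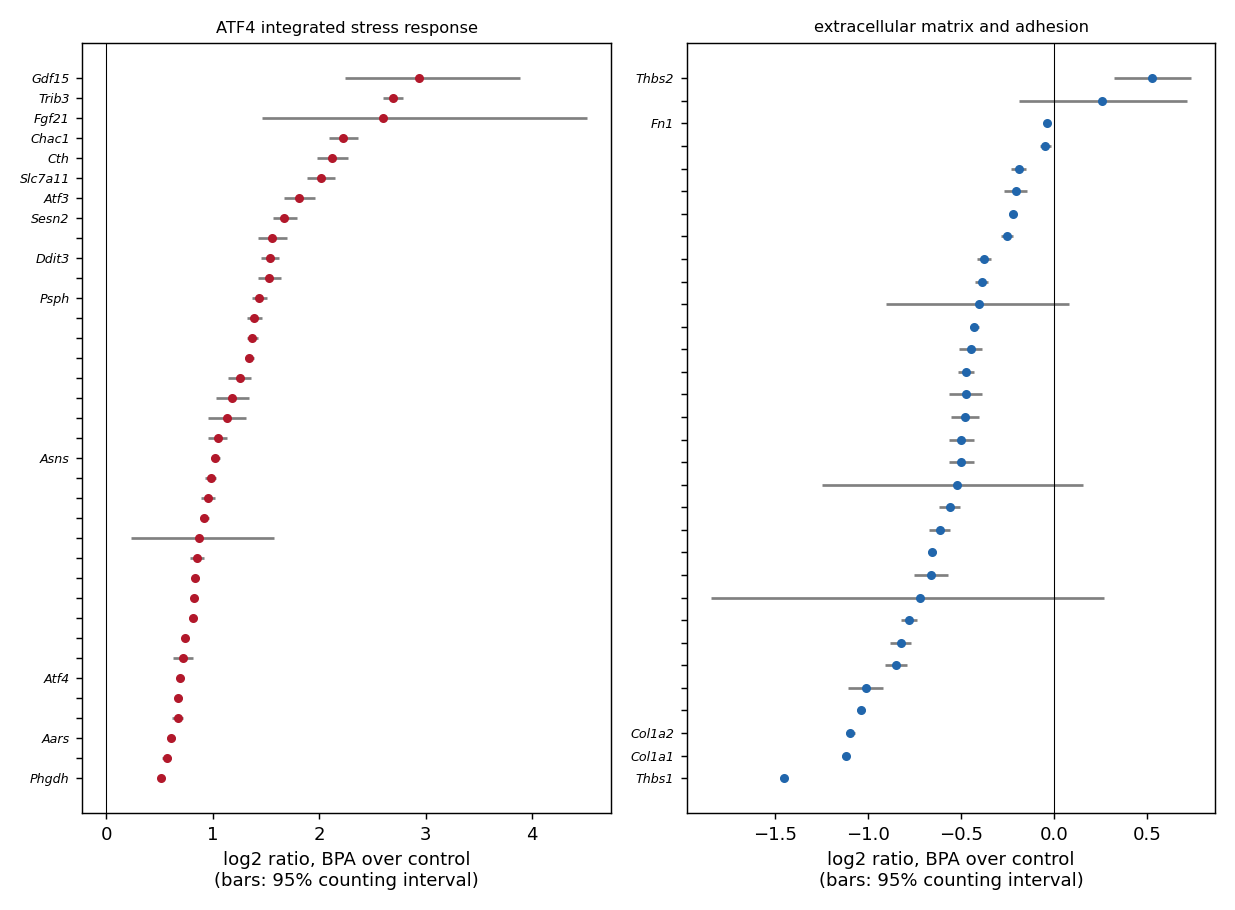
Log2 ratio of BPA over control (horizontal axis) for each measured gene of the ATF4 integrated stress response list and of the extracellular matrix and adhesion list, with some genes named, 1 mRNA library per group, with bars for the 95% counting interval. All 36 ATF4 genes lie above 0, from 0.51 for Phgdh to 2.94 for Gdf15, and 30 of 32 matrix genes lie below 0, down to -1.45 for Thbs1.

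Growth and inflammatory genes also stood apart. Immediate early genes had a median of -0.25 over 27 at percentile 0.06, with Egr2 at -1.73, Egr3 at -1.35 and Ctgf at -0.99 against Klf4 at 1.23. NF-κB and inflammatory mediators had a median of -0.24 over 20 at percentile 0.50, with 3 at least 2-fold higher and 3 lower, and of -0.45 over 16 with the stricter filter, below all random lists. The receptor Il1rl1 was at -1.85 and Tnfaip2 at 2.44. Ccl20, with 0 and 16 reads, was 4.94-fold higher with 3 counts in place of 0, and its interval began at a log2 ratio of 1.84. Glycolysis and hypoxia genes had a median of -0.22 over 31 at percentile 0.32, with Adm at -1.13 and Egln3 at -0.84 against Ero1l at 1.17 and Ndrg1 at 1.01. Mitosis genes had a median of -0.18 over 40 at percentile 0.47, none at 2-fold, with Bub1 at -0.59, Foxm1 at -0.55, Plk1 at -0.42 and Ccnb2 at 0.42. DNA replication genes had a median of 0.09 over 39 at percentile 99.95, with the flap endonuclease Fen1 at 1.61, E2f1 at 0.52, Tk1 at -0.68 and Rrm1 at -0.61. Replication-dependent histones had a median of -0.41 over 22 at percentile 1.22, from few reads, such as 38 and 5 of Hist1h4c. Their percentile was 13.2 over 7 genes with the stricter filter, inside the random range, where it also lay with no filter. Placing Ifi44 and Ccl20 at their folds with 3 counts in place of 0 left their lists' medians where they were, since both lie above the median.

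The other lists with at least 5 measured genes lay inside the range of random lists. Germ cell lists held few measured genes. Germ cell identity markers had 2 measured of 20, Piwil2 with 7 and 13 reads and Nanos3 with 3 and 7, and no median was computed. Meiotic spermatocyte markers had a median of 0.30 over 10 of 36, with Hspa2 at 0.40 and Hormad2 with 4 and 17 reads, spermatid markers 0.72 over 5 of 21, with Tssk1 at 0.90 from 10 and 21 reads, and spermatogonial markers 0.50 over 7 of 16, with Etv5 at 1.05 and Kit at -1.09 from 7 and 3 reads. Leydig cell markers had a median of 0.11 over 6, with Nr5a1 at 0.26, and macrophage and leukocyte markers 0.57 over 7, with Cd74 at 2.85 (1.32 to 6.48) from 2 and 22 reads. Epithelial markers had 3 measured of 11, Krt7, Krt8 at -0.83 and Krt19 at 0.25, too few to compare with random lists. Nuclear hormone receptors and estrogen-responsive genes had a median of 0.15 over 19, with Greb1 at 1.34 from 14 and 40 reads, Igfbp4 at 0.99, and the receptor Esr1 at -0.49. Aryl hydrocarbon receptor genes had a median of 0.15 over 8 (0.25 over 7 with the stricter filter), with the xenobiotic enzyme Cyp1a1 at 1.47, from 521 and 1564 reads, and Cyp1b1 at -0.04.

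Among metabolic and housekeeping lists, the medians were -0.04 over 25 cholesterol synthesis genes, -0.09 over 21 fatty acid and lipid storage genes, with Lpin1 at 0.82, -0.07 over 40 nuclear oxidative phosphorylation genes, with Atp5c1 at -0.81, -0.13 over 46 ribosomal protein genes, with Rps20 at 0.72, and -0.02 over 5 metallothionein and zinc genes, with Mt2 at 1.01. Mitochondrially encoded mRNAs had a median of -0.17 over 13. The exception was mt-Atp6 at -2.64, whose exons overlap mt-Atp8 and mt-Co3. It had 72384 and 12552 reads and these neighbours 82398 and 77595, and the ratio of all of them together was -0.89, which does not show where the reads of mt-Atp6 went. Apoptosis regulators had a median of -0.01 over 27, with Bbc3 at 0.62 and Apaf1 at 0.57 and none at 2-fold. Cyclins and cell cycle inhibitors had a median of -0.12 over 23, with Cdk6 at -0.78, and DNA and histone methylation enzymes -0.03 over 17, with Dnmt3b at -0.44. The miRNA processing and effector proteins had a median of -0.05 over 17, with the nuclease Drosha at -0.49, Tarbp2 at -0.46, Dis3l2 at 0.38 and Ago4 at 2.52 (1.38 to 4.44) from 5 and 36 reads. Factors of circRNA formation and decay had a median of -0.15 over 21, with the editing enzyme Adar, an interferon-inducible gene, at 0.80, Mbnl1 at -0.47 and Rbm20 at 0.91, the last from 3 and 7 reads. In all, 18 of 36 tested lists stood apart, 8 higher and 10 lower, where 1.8 would if their members were drawn at random. Genes of a list can vary together and some lists share members. The number that would stand apart between 2 cultures treated alike is therefore not known.

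**Figure D2:**
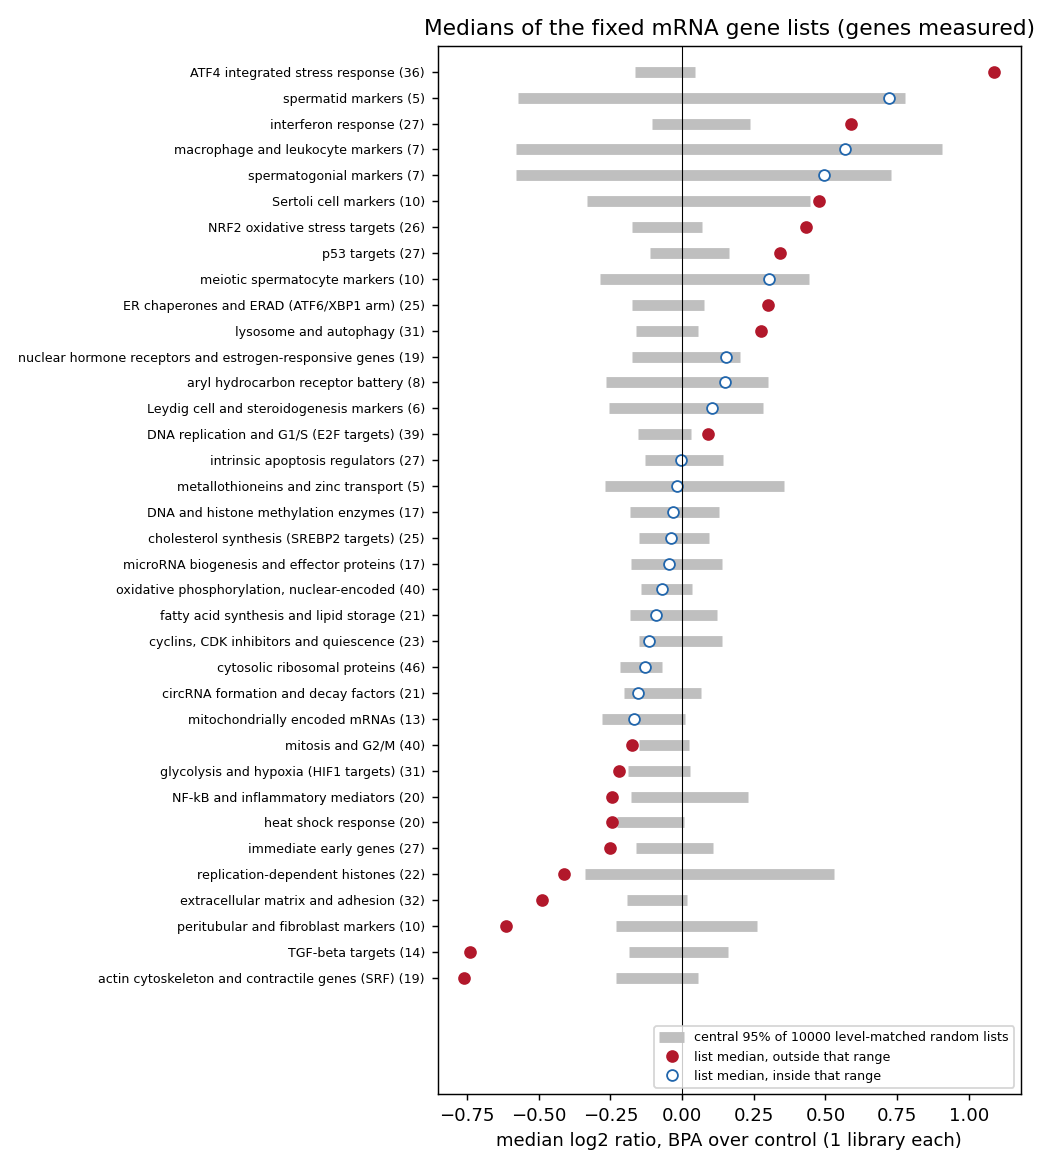
Median log2 ratio of BPA over control (horizontal axis) of the 36 gene lists with at least 5 measured genes, the number measured in brackets, 1 library per group. Grey bars are the central 95% of 10000 level-matched random lists, and filled points, from 1.09 for the ATF4 list to -0.76 for the actin list, lie outside them.

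Over all genes, 1160 of 16870 were at least 2-fold higher and 778 at least 2-fold lower in the BPA library, 347 and 183 of them at least 4-fold. The counting interval excluded equality for 921 and 591. Of the counted genes 187 and 90 had 0 reads in the other library. With 3 counts in place of 0, all of these were still at least 2-fold. The filter on the reads of both libraries together ensured that outcome, so it is no evidence that these genes changed. Most of the 1160 and 778 genes had fewer than 50 reads together. Among the 13530 genes with at least 50, 440 were at least 2-fold higher and 277 lower. The most extreme genes by the naming rule were largely those at or near 0 in a library. For those at 0, the fold with 3 counts in place of 0 is given, with the log2 end of the interval nearest equality. Higher were Eif3j2, a translation initiation factor copy (chromosome 18, 43475418 to 43477796), with 0 and 1045 reads, 322-fold (from 8.03), and RP23-325D10.3 with 0 and 549, 169-fold (from 7.10). Tagap had 0 and 153, 47.2-fold (from 5.25), and Flt3l (ENSMUSG00000089989) 0 and 134, 41.3-fold (from 5.05). Pet117 had 1 and 433 reads (7.68, interval 6.16 to 13.95), and Pde2a (ENSMUSG00000110195) was at 5.05 (3.87 to 7.74). The carbonic anhydrase Car6 (chromosome 4, 150187015 to 150201332) had 16 and 545 reads (4.90), the actin-binding Avil 6 and 181 (4.60), the calcium pump Atp2a3 7 and 153 (4.16) and the sterol acyltransferase Soat2 17 and 226 (3.55). Lower were RP23-62O7.9 with 1509 and 0 reads, 543-fold (from -8.79), and Usp50, also with 0 in the BPA library, 52.2-fold (from -5.39). So were the protocadherins Pcdhgb1 with 3224 and 5 (-9.17) and Pcdhgb8 with 269 and 5 (-5.59), Exosc6 with 751 and 26 (-4.91) and B3gnt2 with 857 and 56 (-4.02). Krt7 was at -3.51, the lipopolysaccharide receptor Tlr4 (chromosome 4, 66827584 to 66930284), with 427 and 48, at -3.24, and Zfp62 at -2.65.

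On GRCm38, Tagap lies on chromosome 17 (7926000 to 7934897), Pet117 on 2 (144368996 to 144373721), RP23-325D10.3 on 7 (127785608 to 127803802), Flt3l on 7 (45125922 to 45136231), Pde2a on 7 (101421691 to 101512827), Avil on 10 (127000709 to 127020994), Atp2a3 on 11 (72961169 to 72993044) and Soat2 on 15 (102150526 to 102163469). Of the lower genes, Pcdhgb1 and Pcdhgb8 lie on 18 (37680233 and 37761801, both to 37841870), Usp50 on 2 (126709096 to 126783470), Exosc6 on 8 (111056339 to 111057664), B3gnt2 on 11 (22759738 to 22860961), Krt7 on 15 (101411043 to 101430313) and Zfp62 on 11 (49203292 to 49218816), and RP23-62O7.9 is not in the annotation used here. Several of these genes share exons with a neighbour on the same strand, and their reads are uncertain for that reason. They are Pcdhgb1 and Pcdhgb8 with other protocadherins, Exosc6 with the stress gene Aars, Pet117 with Csrp2bp, RP23-325D10.3 with Hsd3b7 and Setd1a, and B3gnt2 and Usp50. Pde2a shares exons with a second entry of that symbol, and Flt3l with a second entry of its symbol and with Rpl13a. B3gnt2 had 857 and 56 reads where its overlapping genes had 69 and 1093, and the gene that overlaps Usp50 had 1 and 75. Eif3j2 overlaps a gene with 1 read in each library. Car6, Avil, Atp2a3, Soat2, Krt7 and Tlr4 overlap no other gene. Of mRNA genes, the authors' deposited table gave 147 a p-value under 0.05 and 0 an adjusted value under 0.05.

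The miRNA comparison asked the same of small RNA. A single miRNA, miR-148a-3p (chromosome 6, 51269829 to 51269850, from Mir148a), made up 70.5% of control reads and 35.2% of BPA reads, 2767490 and 1214362 reads. Its log2 ratio was -2.68 (-2.69 to -2.68) after TMM scaling. How many miRNAs were counted as higher or lower depended on the scaling. Under TMM 61 of 464 miRNAs were at least 2-fold higher and 68 lower, 47.3% higher, and by share of the total 361 were higher and 13 lower, 96.5% higher. The median of all miRNAs shifted by 1.67 between them, and ratios below are TMM-scaled, that is relative to most other miRNAs. Of the TMM counts, 36 and 59 had intervals that excluded equality, and 53 and 42 were miRNAs with a miRBase-style name. Of 6 higher miRNAs at 0 in control, 2 were at least 2-fold with 3 counts in place of 0.

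The lower miRNAs included both 3p and 5p arms. Of those lower by both scalings, miR-151-3p (chromosome 15, 73254820 to 73254840) had 112735 and 46972 reads, a ratio of -2.76 (-2.77 to -2.74) and -1.08 by share. miR-30e-3p was at -2.37 and -0.68, miR-28a-3p at -2.11 and -0.43, miR-582-3p at -2.13 and -0.45, miR-3066-5p at -2.23 and -0.56, and the tumour-linked miR-182-5p, with 152036 and 117316 reads, at -1.87 and -0.19. The unnamed miRNAs 11_16688 and 4_5085 were at -3.09 and -2.31, and -1.41 and -0.64 by share. Other miRNAs were lower by TMM and higher by share, among them miR-10a-5p (-1.12 and 0.56), miR-183-5p (-1.53 and 0.16), miR-221-5p (-1.51 and 0.17) and miR-143-3p (-0.66 and 1.02). Higher by both scalings were miR-3473b with 10 and 151 reads (2.39), miR-34b-3p, of a p53-induced family, with 6 and 63 (1.85, 0.69 to 3.40), the liver miRNA miR-122-5p with 19 and 161 (1.57, 0.90 to 2.36), miR-700-3p (1.56), miR-344d-3p (1.56), miR-344-3p (1.52), miR-690 (1.28) and miR-669a-3p (1.27). Abundant miRNAs higher by both included let-7f-5p (chromosome 13, 48537889 to 48537910, 1 of 2 loci), with 2.43% and 10.3% of reads, at 0.40 and 2.08, let-7i-5p at 0.27 and 1.95, and miR-30a-5p at 0.85 and 2.53. The smallest miRNA p-value in the authors' deposited table was 5.08e-05, for 11_16688, with an adjusted value of 0.0473, the only one under 0.05.

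**Figure D3:**
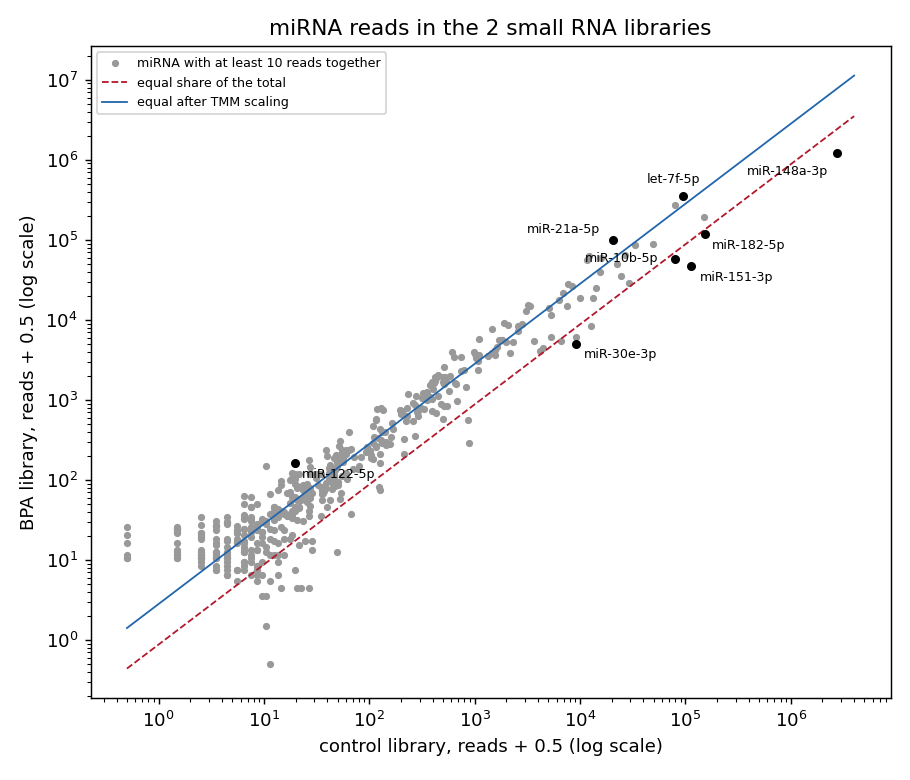
Reads of the 464 miRNAs in the control (horizontal axis) and BPA (vertical axis) libraries, each plus 0.5 on log scales, 1 library per group. The dashed line is an equal share of the total and the solid line is equality after TMM scaling. Below both lie miR-148a-3p, with 2767490 and 1214362 reads, miR-151-3p and miR-30e-3p. Between them lie miR-10a-5p, which is not labelled in the plot, and others.

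No miRNA family stood apart from level-matched random lists, 0 of 15 tested, where 0.75 would if members were drawn at random. However, a family of 8 shifted by 0.5 would mostly have been missed. The miR-17-92 and paralogous clusters came nearest, with a median of 0.37 over 14, at the edge of the random range and just past it with a pseudocount 5 times smaller (0.38), with miR-25-3p at 0.76 and miR-106b-3p at -0.99 (0.69 by share). The medians were 0.12 over 15 let-7 members, 0.38 over 4 of the miR-34 family, with miR-34c-5p at 0.27 and miR-34a-5p at 0.03, 0.16 over 9 of miR-15/16, with miR-16-5p at 0.54, 0.23 over 5 of miR-29, with miR-29a-3p at 0.13, 0.26 over 9 of miR-30 and 0.15 over 11 of the miR-23/24/27 clusters, with miR-27a-5p at -0.59 (1.09 by share) and miR-27b-3p at 0.36. They were 0.14 over 4 of miR-181, 0.00 over 10 mesenchymal miRNAs, 0.60 over 5 serum-abundant miRNAs, 0.99 over 3 of the imprinted Dlk1-Dio3 cluster and 0.23 over 30 of the Sfmbt2 cluster. The medians that were negative, -0.06 over 4 of the miR-221 cluster, -0.06 over 17 stress-responsive miRNAs and -0.09 over 4 of the X-linked testis cluster, were positive by share of the total (1.60, 1.62 and 1.49). The muscle list had 2 measured members, miR-206-3p at 0.58 and miR-1a-3p at 0.99, and the epithelial miR-200 family and the pluripotency clusters had 0. With the filter 5 times stricter the median of the miR-23/24/27 clusters was 0.36 and that of the Sfmbt2 intron cluster 0.07, and with no expression filter that of the X-linked testis cluster was 1.13, all inside the random range.

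The circRNA comparison asked which back-splice products differed. The 9158 circRNAs came from 3954 host genes, 8841 of them exonic, 183 intronic and 134 of exons with introns, and 714 had a circBase entry. There were 1.36 times as many events with BPA, and 6485 circRNAs were detected against 4706 in control, 2033 in both. Of these, 60.5% and 55.7% rested on 1 event. With the BPA library thinned to 12909 events, 5349 were still detected on average over 200 draws (5281 to 5408). Among 457 circRNAs past the filter, 81 were at least 2-fold higher and 44 lower after TMM scaling (64.8% higher). The split was 65 to 59 (52.4%) by total events, which moved the median by -0.16. It was 125 to 32 (79.6%) with DESeq2 size factors, which moved the median by 0.26. Those factors were equal for the 2 libraries, so the events were left unscaled and their larger number with BPA was kept. The interval excluded equality for 29 and 20 of the 81 and 44. In simulated libraries 20.3% of unchanged circRNAs had 2-fold ratios from counting and scaling error together, and their median was 0.14, close to the 0.18 of the 457 measured circRNAs, so the excess of higher ones is not separated from scaling error.

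Named circRNAs were exonic. The exonic circRNA of Dcbld2, a membrane receptor gene (chromosome 16, 58424561 to 58433463), had 21 and 71 events and a ratio of 1.46 (0.76 to 2.26), against 0.15 for the Dcbld2 mRNA. That of Esyt2 (chromosome 12, 116317830 to 116324210), with 9 and 28 events, was at 1.32 (0.24 to 2.63), and that of the deadenylase gene Cnot6l (chromosome 5, 96128943 to 96134132), with 72 and 166, at 0.93 (0.52 to 1.35), against 0.04 and -0.40 for their mRNAs. Intervals of the next, those of Cep112 (0.97), Cpq, Hnrnpll and Dcun1d1 (0.88 each), included equality. Lower were circRNAs of the receptor gene Fgfr2 (chromosome 7, 130241200 to 130242644), with 24 and 9 events, at -1.63 (-2.98 to -0.53), with its mRNA at -0.70, Atxn2 at -1.24, Dtnb at -1.14, the ubiquitin ligase gene Nedd4 at -1.08, Lrp6 at -1.07, Samd4 at -1.02 and Snx5 at -0.93, and that of Myh9 at -1.05, whose interval included equality. All of these kept their direction by total events and unscaled. Leaving the events unscaled moves the intervals upward by about the 0.26 by which the median moved. The upper TMM limits were -0.18 for Dtnb, -0.11 for Nedd4, -0.19 for Lrp6, -0.04 for Samd4 and -0.13 for Snx5. Unscaled, those intervals would therefore include equality. That of Atxn2, with an upper limit of -0.26, would lie at the edge, and that of Fgfr2 would exclude it.

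The most abundant circRNA, of Nfix (chromosome 8, 84771784 to 84772315), had 441 and 506 events and a ratio of -0.08 (-0.26 to 0.11). That ratio was 0.20 unscaled and -0.25 (-0.43 to -0.06) by total events, so its direction depends on the scaling, and the Nfix mRNA was at -0.47. That of Pvt1, a non-coding RNA gene (chromosome 15, 62107148 to 62107465), had 287 and 225 events and -0.62 (-0.88 to -0.37), while linear Pvt1 was at 0.48 (0.26 to 0.71). Ptchd4 (chromosome 17, 42377160 to 42377640) was at -0.84 in circRNA and -0.73 in mRNA, Rras2 at 0.38 and 0.09, and the circRNA of Zfx at -0.19, or 0.08 unscaled. Of well-known circRNA hosts, Hipk3 was at 0.14 (-0.03 by total events), Elf2 at 0.23, Camsap1 at -0.31 and Dennd1b at 0.30, each with an interval that included equality. The smallest circRNA p-value in the authors' deposited table was 0.0019, for Cnot2, and the smallest adjusted value 0.865.

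The last comparison asked whether circRNAs followed the mRNA of their hosts, as RNA of each kind came from the same cultures. Across 687 host genes with both measured, the circRNA and mRNA ratios were nearly unrelated, with Spearman's rho 0.09 (bootstrap 95% interval 0.01 to 0.17) and Pearson's r 0.06, across genes that are not independent replicates. Of 125 hosts with circRNA at least 2-fold higher 122 had mRNA within 2-fold, as had 52 of 53 hosts with circRNA at least 2-fold lower. The signs were the same for 374. Only 2 host mRNAs were 2-fold higher and 5 lower, and the interval of the circRNA ratio excluded equality for 95 hosts, so counting error limits how close a relation could appear.

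**Figure D4:**
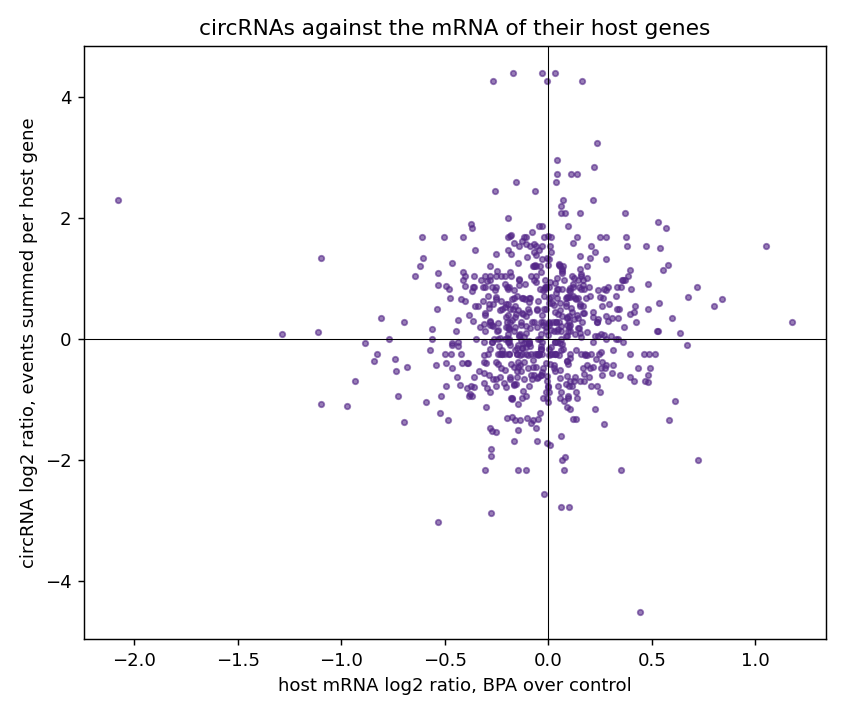
Log2 ratio of BPA over control of circRNA events summed per host gene (vertical axis) against the mRNA ratio of the host (horizontal axis) for 687 host genes, each a point, from 1 library per group. Spearman's rho was 0.09, and the circRNA ratios spread more widely than the mRNA ratios, of which 7 reached 2-fold.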

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

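Of the alternatives in this part, the omission of overlapping genes, TMM on the recovered mRNA reads, the omission of members shared with the ATF4 list, named miRNAs only and the filter at 5 events were chosen after seeing the data, and the others before. Of 886 comparisons of 203 named features 781 stayed within their counting interval, 102 moved beyond it, and 3 with a called direction reversed. Those were miR-10a-5p at 0.56, miR-183-5p at 0.16 and miR-221-5p at 0.17, all scaled by total count. Of the list medians 279 comparisons were the same, 2 came to stand apart and 4 no longer did. Of the summary values 49 comparisons were judged the same and 28 were not. The same meant within 1.5 times for counts, equal or within 1.5 times for numbers of lists, and within the bootstrap interval for Spearman's rho.

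Without a filter, mRNA counts were 2978 higher and 2381 lower, miRNA counts 327 and 185, and circRNA counts 4754 and 2899, since more features with few reads were compared. With a filter 5 times stricter, at least 50 reads or events together, they were 440 and 277, 23 and 30, and 2 and 0. The features compared were 13530, 295 and 51 in place of 16870, 464 and 457. The counts fell by a larger share than the features compared. Most features counted as 2-fold with the main filter thus had fewer than 50 reads or events together. By total count miRNAs were 361 higher and 13 lower. Requiring the interval to exclude equality left 36 higher miRNAs, and 29 higher and 20 lower circRNAs. Named miRNAs alone gave 42 lower. For circRNA, DESeq2 size factors, which left the events unscaled, gave 125 higher. A pseudocount 5 times larger gave 53, summing by symbol 128, and the filter at 5 events 319 higher and 174 lower. With a pseudocount 5 times smaller 1 miRNA family, miR-17-92, stood apart. At 2 events or more 2087 circRNAs were detected in control and 2563 with BPA, and at 5 or more 466 and 666. The cause was not tested where none is given. No paired analysis was possible because each group had 1 library and no test was made.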

Other observations

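Of the tests below, those of the hairpin amount, of the first base in 5p arms and of the totals without miR-148a-3p were chosen only after the result was seen, as were the thresholds that define genes at or near 0 in 1 library and the rule by which the share with a copy was judged.

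The 5p and 3p arms of the same miRNA hairpin often had different ratios, such as 0.84 and -2.37 for miR-30e, 0.85 and -1.79 for miR-30a, and -1.51 and 0.02 for miR-221. Among 50 hairpins with both arms measured, the interval of the difference excluded 0 in 32, which a change in the amount of the hairpin as the whole cause does not allow, though the intervals treat PCR reads as independent. Recovery that depends on the first base may contribute, since the range of the medians by first base lay at percentile 99.17 of shuffled classes, with miRNAs that begin with C at -0.41. That difference was -0.60 (-0.79 to -0.29) in 3p arms and 0.10 (-0.75 to 0.38) in 5p arms, so the 5p arms leave it undecided, and Spearman's rho with GC content, -0.149 (-0.270 to -0.0246), decided nothing either. Whether BPA altered which arm is kept cannot be told from 1 library per group.

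Among abundant mRNA genes, 32 had at least 100 reads in the higher library and a log2 ratio of at least 3 in size, and 31 of them are annotated. Reads assigned to an overlapping gene are a candidate explanation for many, since 58.1% shared exons with another gene on the same strand, against 9.68% (up to 22.6%) of level-matched genes. Near-identical copies were found for 22.6%, against 25.8% (up to 41.9%) of matched genes, which is no excess. Copies were common among the matched genes, so this comparison cannot exclude them as a cause. They stay open for single genes such as Eif3j2 and Tagap. The predicted genes Gm21451 and Gm21887, with 2009 and 1517 reads in control and 0 with BPA, also have a copy. For the 8 genes with neither, among them Krt7, Tlr4, Car6, Avil, Atp2a3 and Soat2, BPA and another difference between the cultures cannot be told apart.

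The ATF4 list, at 1.09, kept its place above all random lists after removal of the trend on GC content (1.09) and of that on transcript length (1.07), so neither bias was the whole cause. Of the 18 lists that stood apart, 17 still did without the GC trend, the heat shock list passing from -0.24 (random lists -0.23 to 0.00) to -0.23 (-0.25 to -0.01) because its median and the random range both moved slightly. Without the length trend 19 did, with cyclins and cell cycle inhibitors added at -0.18 (-0.17 to 0.12). An effect of BPA and any other difference between the cultures cannot be told apart with 1 library per group.

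As a hypothesis, targets of a miRNA would lie opposite to it. The median of mRNAs with an 8mer site in the 3′ untranslated region was at percentile 74.44 of matched genes for miR-148a-3p and 66.13 for miR-10a-5p, both lower after TMM scaling, and at 17.8 for let-7f-5p and 9.96 for miR-21a-5p, both higher, so none of the 4 showed it. For miR-182-5p, lower as well, it was at 1.08, on the side opposite to the hypothesis. The smallest shift that these comparisons could detect was not computed, so the 4 inside the random range cannot tell whether targets responded. By share of the total miR-10a-5p was higher (0.56), so the direction of its hypothesis depends on the scaling. With miR-148a-3p left out of the totals, the median ratio of the other 463 miRNAs was 0.58 in place of 1.70, so its lower share was not the whole cause of the shift by share of the total.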
